A study of Mus musculus with 2 samples.

How the data were processed

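Submandibular glands of adult mice, 12 weeks of age, were dissociated whole into single cells and run on the 10x Genomics Chromium platform, which counts the 3' ends of transcripts in droplets, each carrying a cell barcode. There was 1 library from a p63 wild-type mouse and 1 from a p63 KO mouse. The labels do not say how or when p63 was removed, which exons were deleted, or whether glands were pooled. The submitters' processing notes name Cell Ranger 2.1.0, bcl2fastq 2.19.1, Seurat 3.1.2 and the build mm10, without giving each tool's role. The authors deposited raw UMI counts per gene and barcode; a UMI is a tag that marks 1 captured molecule. The rule by which the deposited barcodes were chosen is not given in the sources used here. Both tables held whole numbers for 27998 Ensembl genes, of which 27645 received a symbol from GENCODE mouse M21 and 353 kept their identifier; gene positions refer to GRCm38.

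Depth differed between the libraries. The wild-type library held 8811082 UMIs in 1970 barcodes, with a median of 3189 UMIs and 1123 genes per barcode, and the KO library 11828669 UMIs in 4726 barcodes, with a median of 2041 UMIs and 740 genes. Their median mitochondrial shares were 5.57% and 14.8%, and ribosomal protein shares 15.8% and 9.81%. Barcodes with at least 200 genes and under 20% mitochondrial UMIs were kept, which left 1663 wild-type cells (84.4% of barcodes, 95% exact binomial interval 82.7 to 86.0%) and 2423 KO cells (51.3%, 49.8 to 52.7%). Kept cells had medians of 3406 and 2088 UMIs. The shallowest deposited barcode held 2175 UMIs in the wild-type and 1076 in the KO library. No kept cell had fewer than 1000 UMIs, so every cell could be thinned at random to that number.

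Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes without Trp63 gave 30 principal components, and a graph of 15 neighbours was partitioned at Leiden resolution 1. Both libraries were clustered together, and as an alternative each on its own. Clusters were named from 24 marker sets fixed before the data were examined. A name needed at least 3 markers that were 2-fold higher in the cluster than in other cells, with at least 10 UMIs each and 1 of them among its top 50 genes. A cluster stayed unnamed when another set had more genes among its top 10, when it had under 15 cells, or when it was shallow and lacked its set's markers among those 10. These thresholds were set after the clusters had been seen, and names are written with "-like" because they rest on RNA alone. Together, the libraries gave 23 clusters, of which 16 took over 85% of their cells from 1 library; 4 stayed unnamed, with 7.10% of wild-type and 23.3% of KO cells. Clustered alone, the wild-type library gave 15 clusters and the KO library 18, with 8.96% and 7.59% of cells unnamed.

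With 1 library per genotype no test between genotypes was possible, and cells were not treated as replicates. UMIs were summed per class and library and scaled by the class total (CPM). The KO over wild-type ratio was given with the exact conditional 95% interval of a ratio of Poisson counts, and shares of cells with exact binomial intervals. All intervals cover counting error only. In place of a test, a gene passed the size rule when it had at least 50 UMIs in both libraries together and an interval wholly beyond 2-fold. Log2 ratios had 10 CPM added to both sides. For a gene at 0 in 1 library, the fold was taken against a floor of 3 counts in that class. Such folds are written with "at least", but the bound of the 95% interval can lie lower. For Lcn2 in macrophage-like cells of the separate clusters it was 12.5, against 15.7 by the floor. Classes with at least 50 cells in each library were compared, and by the fixed design always basal duct-like and myoepithelial-like cells. The median log2 ratio of each of 21 gene lists fixed in advance was set against 10000 random lists matched on expression, over members with at least 10 UMIs and for lists with at least 5 such members. This percentile describes these libraries and is not a test.

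Named genes followed a rule fixed in advance: Trp63 and Fst, then the 10 highest and 10 lowest log2 ratios among genes past the size rule in each of the main epithelial classes (5 each way in other classes). Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out. Of each list, the members with the most UMIs and those past the size rule were eligible. Free RNA in droplets was gauged in immune-like cells, meaning the macrophage- and NK-like clusters found in each library separately (129 wild-type and 356 KO cells). Their cell mix differed: in the joint clusters, 72 wild-type and 1 KO cells lay in the macrophage-like cluster, and 13 and 266 in an unnamed cluster with neutrophil genes among its top 10. Endothelial-like cells had been meant for this purpose and were replaced after their values were seen, because those of the wild-type library held 170 Krt14 UMIs and 87 of the red cell gene Alas2.

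Several other choices came after the values were seen. Basal duct-like cells were compared from the separate clusters, since the joint class held 4 KO cells. Pairs of clusters were made by taking, in each library, the separate cluster with the highest level of Smgc, Mucl2 or Wfdc18. Each pair was also a mutual best match by the correlation of profiles over 10189 genes with listed genes left out. An ionocyte-like comparison was dropped because the wild-type cluster of that name paired best with an unnamed KO cluster (r = 0.60 across genes, which are not replicates). Separate clustering was repeated without the p63-associated, TGF-beta, activin and cell cycle lists. Its clusters were still named by the full marker sets, keratins included. Doublets (2 cells in 1 droplet) were kept; Scrublet called 1 wild-type and 4 KO cells, so leaving out the 5% of cells with the highest scores was added.

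Alternatives fixed in advance were no cell filter, a filter of at least 500 genes and under 10% mitochondrial UMIs (1319 and 1499 cells), Leiden resolutions 0.5 and 2, joint clustering without those lists, thinning, leaving out Scrublet calls, and shares of epithelial cells alone. They also included scaling by the trimmed mean of M values (TMM) or by a total without secretory products, UMI minimums of 20 and 200, a 1.5-fold rule, 1 or 50 CPM added before the log, and a minimum of 50 UMIs for list members. The size rule was tested on simulated Poisson sums with 200 changed genes. At the depth of the myoepithelial-like, basal duct-like and granular convoluted tubule-like sums it recovered 100, 95 and 92 of 100 genes raised 4-fold, but 40, 48 and 38 of 100 genes lowered to 0.25 of their level, with 0 in the wrong direction and 0 unchanged genes past the rule. Intervals covered the simulated ratio for 95.3 to 95.5% of genes. Of 200 random lists, 2, 7 and 8 fell outside the middle 95% of the random lists at these depths. Remaining tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.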

Results

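Gene expression was measured in single cells of the submandibular gland, a major salivary gland of the mouse, in 1 p63 wild-type and 1 p63 KO library. p63, encoded by Trp63, is a transcription factor of basal epithelial cells. The series title links it to the proliferation of salivary progenitor cells and to follistatin (Fst), a secreted protein that binds activins. The wild-type library held 8811082 UMIs in 1970 barcodes and the KO library 11828669 in 4726, of which 1663 and 2423 cells were kept, with medians of 3406 and 2088 UMIs. At least 20% of UMIs were mitochondrial in 12.4% (11 to 13.9%) of wild-type and 40.7% (39.3 to 42.1%) of KO barcodes. Xist had 10548 and 9386 UMIs and 4 Y-linked genes together 0 and 1, so both libraries had the profile of female animals. None of the differences given here has a replicate check, and all intervals cover counting error only.

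Trp63 (ENSMUSG00000022510; GRCm38 chromosome 16, 25683763 to 25892102, plus strand) was the targeted gene. Over all kept cells it had 149 UMIs in the wild-type and 20 in the KO library, or 18.8 CPM (15.9 to 22.1) against 2.91 CPM (1.78 to 4.50), a level 6.45-fold lower in the KO library (4.03 to 10.9). Trp63 UMIs were found in 7.28% (6.07 to 8.63%) of wild-type cells and 0.784% (0.473 to 1.22%) of KO cells, and in 1.74% and 0.206% after thinning to 1000 UMIs per cell. In immune-like cells, with medians of 2600 and 1493 UMIs, 1 of 129 wild-type cells (0.775%) and 0 of 356 KO cells had a UMI; the upper limit for the latter is 1.03%. After thinning, both libraries had 0 immune-like cells with a Trp63 UMI. The mix of classes enters the level over all cells. Basal duct-like cells made up 22.4% of wild-type and 4.83% of KO cells in separate clustering. Of the 19 KO cells with a Trp63 UMI, 13 were myoepithelial-like. In that class, 4.88% of cells of each library held one after thinning. Levels within these classes are given below. The tags come from 3' ends, so they check the deletion only if it removed that part of the gene, which the labels do not state.

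The first comparison asked how basal duct-like cells, which line the outer layer of the ducts, differed between genotypes. Krt5, Krt15 and Krt14, keratins of basal epithelium, were lower in the KO cells, as were Ptn, a secreted growth factor, and Igfbp5, an insulin-like growth factor binding protein. Lcn2, an iron-sequestering protein of innate defence, Ctsl, a lysosomal protease, and Txnip, a regulator of thioredoxin, were higher. The comparison used 372 wild-type and 117 KO cells from clusters found in each library separately, with medians of 3218 and 2600 UMIs. Of 3799 genes with enough UMIs, 72 were higher and 78 lower in KO cells past the size rule; with TMM scaling the split was 42 and 114, as that scaling moved the median over all genes from 0.05 to -0.12 log2.

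Krt5 (chromosome 15, 101707070 to 101712898) had 463 UMIs in wild-type and 6 in KO basal duct-like cells, a 20.5-fold lower level (9.33 to 56.0). Krt15 (chromosome 11, 100131758 to 100135928) had 631 and 0 UMIs, at least 55.8-fold lower against the floor. Krt14 had 3232 and 359 UMIs and was 2.39-fold lower (2.14 to 2.67), whereas Krt17, with 2520 and 506 UMIs, stood at 1.32-fold lower (1.2 to 1.46) and did not pass the rule. Since keratins helped to define these clusters, the cells were also grouped without the listed genes (410 and 112 cells). There Krt5 was 21-fold lower (8.95 to 65.0) and Krt15 at least 45.6-fold lower. These clusters were still named by the full marker sets, with Krt14 and Krt17 among the markers of the KO cluster. Keratins thus still helped to choose the cells. Krt14 then had a 2.18-fold lower level (1.95 to 2.44) and no longer passed the size rule, nor did Trp63 at 4.69-fold (1.77 to 17.6). Trp63 itself had 88 and 4 UMIs, 5.83-fold lower (2.20 to 21.9). Krt5 UMIs were found in 60.5% of wild-type and 2.56% of KO basal duct-like cells, and in 25.3% and 1.71% after thinning; in immune-like cells the shares were 1.55% and 0%, and 0% in both after thinning. Krt14 reached 95 CPM in wild-type immune-like cells, against 2201 CPM in basal duct-like cells.

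**Figure D1:**
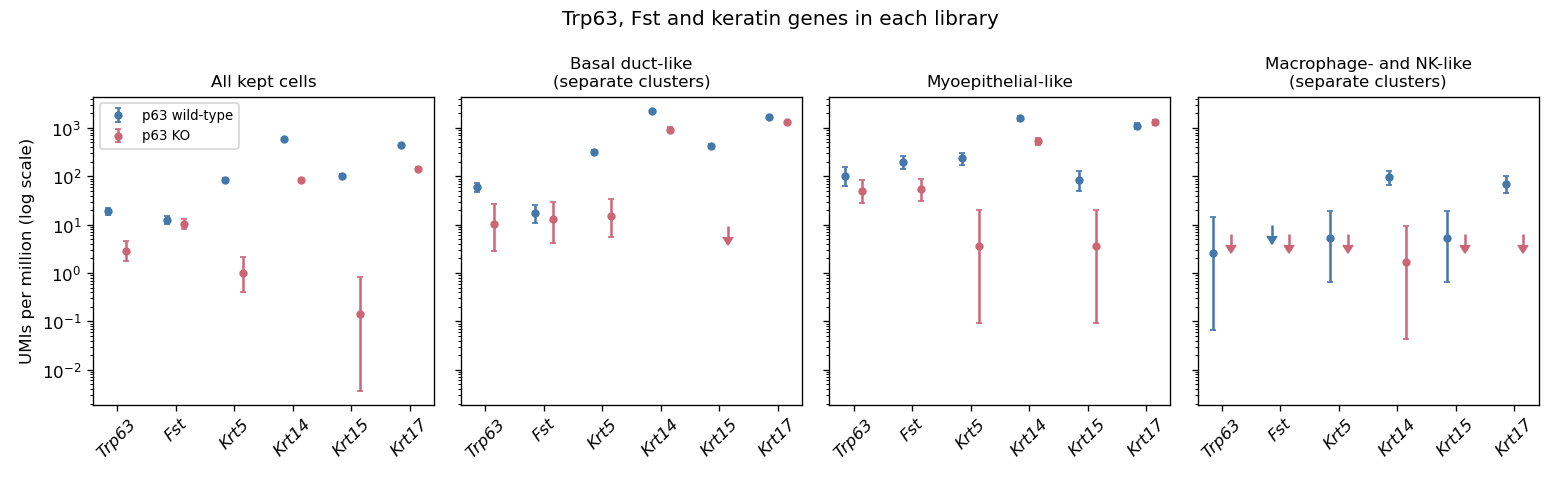
CPM (log scale) of Trp63, Fst and 4 keratin genes in the wild-type library (blue) and the KO library (red), for all kept cells, basal duct-like, myoepithelial-like and immune-like cells. Points are levels of 1 library, bars are 95% Poisson intervals and arrows mark the upper limit of genes with 0 UMIs; Krt5 stands at 315 and 15.4 CPM in basal duct-like cells, while Krt17 stands at 1716 and 1300 CPM.

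Among other genes lower in KO basal duct-like cells, Ptn had 1481 and 3 UMIs, a ratio of 131 (44.7 to 635), and Ccn4 149 and 1, a ratio of 39.5 (6.98 to 1571). Igfbp5 and Sostdc1, an inhibitor of BMP and Wnt ligands, had 291 and 145 UMIs in wild-type and 0 in KO cells, at least 25.7-fold and 12.8-fold lower. Dapl1, Fam213b and the matrix proteoglycan gene Dcn were 15.6-fold (6.03 to 57.9), 11.3-fold (5.87 to 24.8) and 10.7-fold (8.44 to 13.9) lower. Ptn, Dapl1, Fam213b and Dcn moved the same way in immune-like cells, at -1.21, -1.11, -1.09 and -1.27 log2, none past the rule. Smgc, a secretory gene, was 18.7-fold lower (11.9 to 31.2), but it was also lower in immune-like cells, with 2859 and 32 UMIs. Of the higher genes, the casein Csn3 had 0 and 65 UMIs, at least 81.7-fold higher, and Lcn2 was 24.3-fold higher (15.9 to 38.7), with 0 and 96 UMIs in immune-like cells. Cdo1, a cysteine dioxygenase, was 12.3-fold higher (7.57 to 20.9), Fmo2 10.5-fold (6.87 to 16.3), Sash1 8.8-fold (4.96 to 16.2) and Lyz2 8.70-fold (5.41 to 14.4). Ctsl was 7.79-fold (6.92 to 8.77), Tm4sf1 7.26-fold (4.89 to 10.9), Tsc22d3, a glucocorticoid-induced gene, 6.29-fold (5.03 to 7.88) and Txnip 5.95-fold higher (4.62 to 7.71). Ctsl also had a higher level in KO immune-like cells, by 1.92 log2, and Sash1 by 1.29.

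Of 24 measured p63-associated basal genes, 3 were lower past the size rule (Krt5, Krt14 and Krt15) and 21 did not pass it. The list median was -0.22 log2, at the 0.75 percentile of random lists; the percentile was 4.1 with members of at least 50 UMIs, 7.91 at Leiden resolution 2 and 2.69 when each library was clustered without the lists. The same list stood at -0.99 (0 percentile) in endothelial-like and -0.56 (1.34) in immune-like cells. Stress and immediate early genes were higher as a list, with a median of 0.70 at the 100 percentile; Hspa1a, Hspa1b and Socs3 passed the rule at 1.26, 2.05 and 1.83 log2. The same list stood at 0.71 (99.9) in endothelial-like and 0.70 (99.8) in immune-like cells. Cell cycle genes had a median of -0.53 at the 1.58 percentile over 12 members, none past the rule, and -0.24 with members at 0 set to the floor. The percentile was 6.36 with 50 CPM added, 2.95 with TMM scaling and 0 at Leiden resolution 2, where the class took in cycling cells. Summed over the list, the level was 1.28-fold lower (1.09 to 1.5), and 1.33-fold (0.978 to 1.84) after thinning, an interval that includes 1. Hmgb2 stood at -0.06 log2 and Stmn1 at -1.43, with Stmn1 lower past the rule in immune-like cells, at -1.91. The list of cell cycle inhibitors stood at 0.62 (100), with Btg2 at 0.70 and Cdkn1a, which encodes p21, at 0.95 log2, none of 13 past the rule; in immune-like cells Cdkn1a was higher past it, at 1.63, and Btg2 stood at 0.15. Tight and adherens junction genes stood at 0.63 (99.7), with Cldn3 past the rule at 1.74, and hemidesmosome and basement membrane genes at -0.34 (0.355), or -0.26 with members at 0 set to the floor, none past the rule.

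Antigen presentation genes had a median of -0.58 (0.335) in basal duct-like cells, where H2-Ab1, H2-Eb1 and H2-Aa passed the rule as lower; in immune-like cells this list stood at -1.37 (0). Other list medians there were -0.57 (1.03) for interferon response (-0.23 with members at 0 set to the floor), -0.21 (4.96) for oxidative phosphorylation, 0.08 (46.6) for the unfolded protein response and 0.08 (62.6) for inflammatory cytokines and chemokines. Notch pathway genes stood at 0.43 (93.3), Wnt pathway genes at -0.17 (20.9; -0.05 with members at 0 set to the floor), and FGF and EGF family genes at 0.28 (84.9), none past the rule. Salivary progenitor-associated genes stood at 0.11 (56.5), with 3 of 12 lower past the rule, again Krt5, Krt14 and Krt15. Contractile genes stood at -0.07 (50.1).

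**Figure D2:**
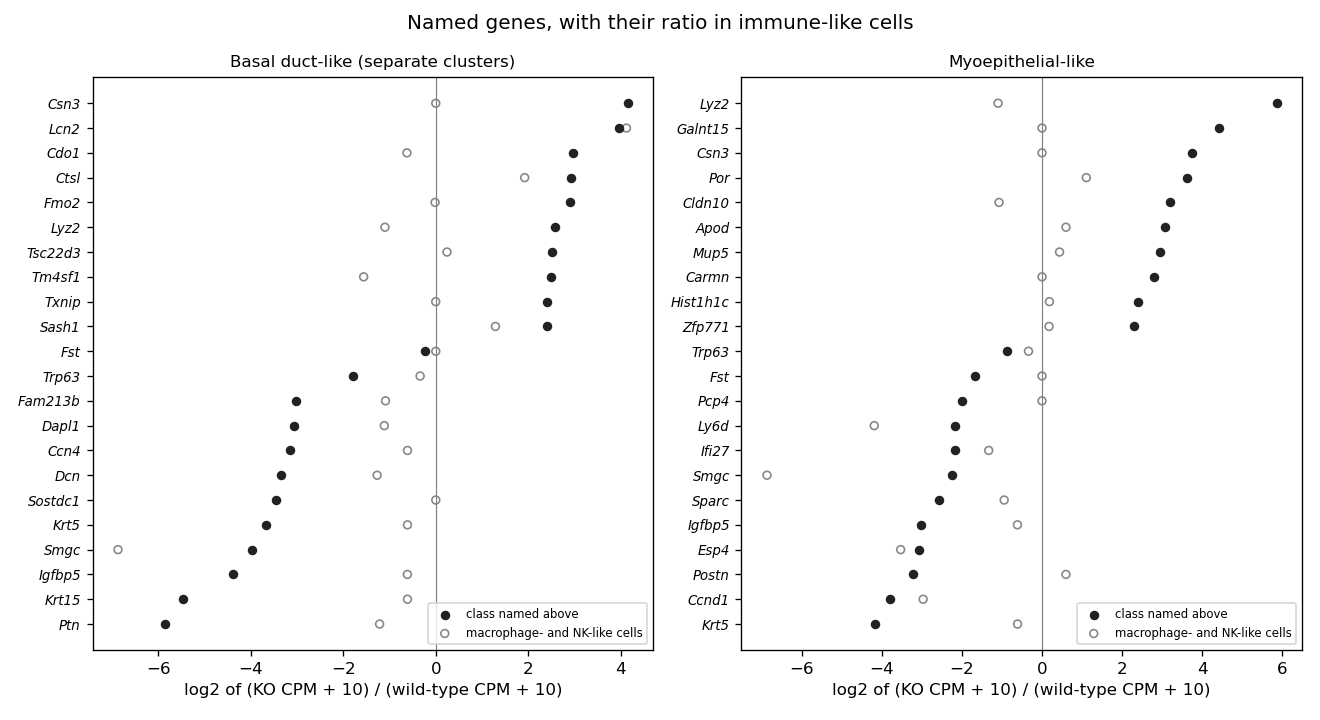
Log2 of KO over wild-type CPM, with 10 CPM added to both, for the named genes of basal duct-like and myoepithelial-like cells (filled points) and the same genes in immune-like cells (open points), 1 library per genotype. Krt15 stands at -5.46 in basal duct-like and -0.61 in immune-like cells, whereas Smgc is lower in both, at -3.97 and -6.87.

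Myoepithelial-like cells, the contractile cells around secretory units, were compared over 41 wild-type and 82 KO cells of the joint clusters, with medians of 4146 and 2373 UMIs. Krt5, Krt14, Postn and Sparc, the latter pair matrix-associated genes, were lower in the KO cells, and Lyz2, Csn3, Cldn10 and Galnt15 were higher. Acta2, the smooth muscle actin that marks these cells, had 814 and 1059 UMIs and a log2 ratio of 0.03. Past the size rule, 48 genes were higher and 27 lower of 1374 with enough UMIs; after thinning 17 passed in all.

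Krt5 had 51 and 1 UMIs in myoepithelial-like cells, a ratio of 64.9 (11.1 to 2612), and Krt14 had 341 and 146, 2.97-fold lower (2.44 to 3.63). Krt17 had 239 and 358 UMIs (log2 ratio 0.23). Trp63 had 22 and 14 UMIs, a ratio of 2.0 with an interval that includes 1 (0.978 to 4.22). Postn was 14.0-fold lower (5.65 to 44.8), Igfbp5 9.41-fold (5.47 to 17.4), Sparc 6.22-fold (4.50 to 8.77) and Pcp4 4.10-fold (3.13 to 5.42). Ccnd1, which encodes cyclin D1, was 22.6-fold lower (8.44 to 85.1), but immune-like cells also had 36 and 2 Ccnd1 UMIs. Esp4, Ly6d, Ifi27 and Smgc were 10.6-fold, 5.02-fold, 5.17-fold and 4.82-fold lower, and in immune-like cells they moved the same way, at -3.53, -4.19, -1.33 and -6.87 log2. Lyz2 had 5 and 525 UMIs, 82.5-fold higher (35.1 to 255), while in immune-like cells, where this lysozyme gene is abundant, its log2 ratio was -1.10. Csn3 was 14.6-fold higher (9.76 to 22.8), Cldn10, a claudin, 11-fold (5.81 to 23.5), Apod 11.6-fold (4.77 to 36.9) and Carmn 10.2-fold (3.76 to 38.9). Galnt15 had 0 and 56 UMIs, at least 14.7-fold higher. Por was 17.3-fold higher (7.19 to 54.3; 1.11 log2 in immune-like cells), Zfp771 5.99-fold (2.86 to 14.5) and Hist1h1c 5.61-fold (3.82 to 8.52). Mup5 had 3 and 48 UMIs, a ratio of 12.6 (4.05 to 63.1).

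The p63-associated list had a median of -0.65 at the 0.01 percentile over 22 members in myoepithelial-like cells, with Krt5 and Krt14 past the rule. Contractile genes stood at -0.53 (0.615), none of 13 past the rule, with Tpm2 at -0.36, Myl9 at -0.53 and Tagln at -0.93 log2. With members of at least 50 UMIs these percentiles were 17.7 and 3.24. Stress genes stood at 0.44 (100), with Junb, Socs3 and Ier3 past the rule as higher.

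Fst (ENSMUSG00000021765; chromosome 13, 114452290 to 114458951, minus strand) and the TGF-beta and activin genes were compared next. In myoepithelial-like cells Fst had 42 and 15 UMIs, 194 CPM (140 to 262) against 54.4 CPM (30.5 to 89.8), a 3.56-fold lower level in KO cells (1.94 to 6.91), whose interval reached below 2, so that it did not pass the size rule. After thinning the fold was 1.60. Fst UMIs were found in 56.1% (39.7 to 71.5%) of wild-type and 15.9% (8.72 to 25.6%) of KO myoepithelial-like cells, and in 14.6% (5.57 to 29.2%) and 9.76% (4.31 to 18.3%) after thinning. None of the 129 and 356 immune-like cells held an Fst UMI, with upper limits of 2.82% and 1.03%. In basal duct-like cells Fst had 25 and 5 UMIs, a ratio of 1.33 (0.498 to 4.43), and over all kept cells 100 and 72 UMIs, a ratio of 1.2 (0.880 to 1.65), both with intervals that include 1. TGF-beta and activin pathway components had a median of -0.23 (10.2) in myoepithelial-like and 0.04 (48.6) in basal duct-like cells, with 0 of 17 and 0 of 23 members past the rule; Tgif1 and Tgfbr1 stood at -0.36 and -0.02 log2 in the former class and 0.04 and -0.06 in the latter. Response genes stood at -0.10 (37.9) and 0.36 (94.2), with Junb past the rule at 1.23 in myoepithelial-like and Id3 at 1.64 in basal duct-like cells. Ccn1, a matricellular gene, stood at 0.99 and 0.61 log2 and Timp3 at 0.33 in both, none past the rule.

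Next, the shares of cells per class were compared. Basal duct-like cells made up 22.4% (20.4 to 24.4%) of the wild-type and 4.83% (4.01 to 5.76%) of the KO library when each was clustered separately. This share follows the names, since Krt5, Krt14 and Krt15, lower in the KO cells, are among the naming markers. KO cells that lost such markers could go uncounted. In the joint clusters the shares were 27.8% and 0.165%. Of the 462 wild-type cells, 405 lay in a cluster with 4 KO cells and 57 in a cluster with 0. The top 10 genes of the latter cluster included Stmn1, Ube2c and Top2a and none of the class's markers. By contrast, 112 of the 117 KO cells above lay in a joint cluster without a name, which held 287 KO cells. Acinar-like cells, which secrete saliva proteins, made up 20.3% (18.4 to 22.3%) of wild-type and 7.06% (6.07 to 8.15%) of KO cells, and granular convoluted tubule-like cells, a duct type that secretes growth factors and kallikreins, 9.86% (8.47 to 11.4%) and 23.4% (21.7 to 25.1%). The difference of 13.5 points in the latter class was 6.17 with no filter (9.44% and 15.6%) and 6.95 with a stricter filter of at least 500 genes and under 10% mitochondrial UMIs (2.12% and 9.07%), and that of -13.3 points in acinar-like cells was -20.3 with the latter filter. Myoepithelial-like cells made up 2.47% (1.77 to 3.33%) and 3.38% (2.70 to 4.18%), with overlapping intervals, but 2.18% and 1.76% with no filter, so the direction turned. Endothelial-like cells made up 2.89% and 13.2%, fibroblast-like cells 0.361% and 4.33%, and intercalated duct-like cells 14.4% and 0.165%. Striated or excretory duct-like cells made up 2.89% and 11.1%, but 2.16% and 0.702% at Leiden resolutions 0.5 and 2, so the direction turned with the clustering. Of the 268 KO cells so named, 251 lay in a cluster with 12 wild-type cells and 0 of the class's markers among its top 10 genes. The intercalated duct-like difference follows the names too: the separate wild-type cluster of 200 intercalated duct-like cells paired best with 258 KO cells named striated or excretory duct-like (r = 0.70 across genes, which are not replicates). Dissociation and recovery of cells can set such shares, and unnamed clusters held 7.10% of wild-type and 23.3% of KO cells.

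**Figure D3:**
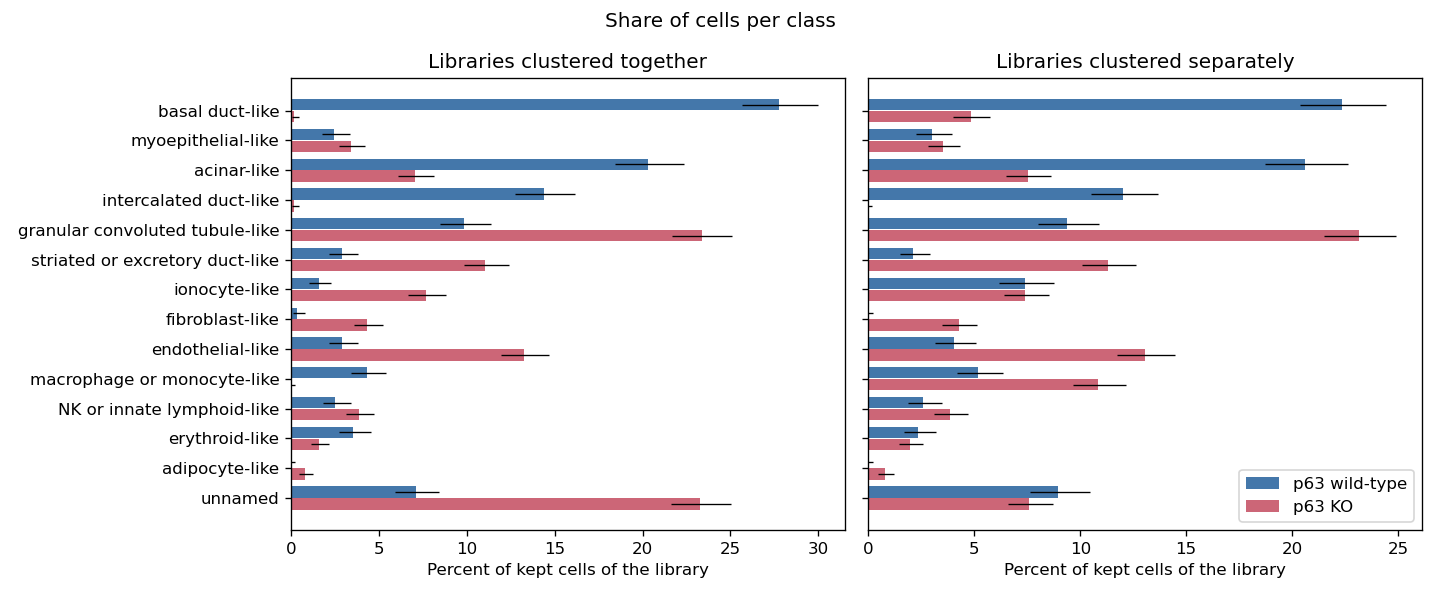
Percent of kept cells per class in the wild-type library (blue, 1663 cells) and the KO library (red, 2423 cells), with libraries clustered together (left) or separately (right); bars are shares of 1 library and error bars 95% exact binomial intervals. Basal duct-like cells stand at 27.8% and 0.165% on the left and at 22.4% and 4.83% on the right.

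In acinar-like cells (338 wild-type and 171 KO), Slpi, a protease inhibitor, Lcn2 and Fgg, the fibrinogen gamma chain, were higher in the KO library, while Smgc, Agr2, a protein disulfide isomerase of secretory cells, and G0s2, an inhibitor of lipolysis, were lower. Slpi had 4 and 290 UMIs, 177-fold higher (68.5 to 655), Fgg was 11.4-fold higher (9.67 to 13.4) and the Lcn2 ratio, with 3 wild-type UMIs, was 82.3 (27.4 to 406). Shroom3 was 19.6-fold (11.9 to 33.9), Bnip3 18.1-fold (11.6 to 29.7), Trp53inp1 14.5-fold (10.1 to 21.6) and Acot1 12.5-fold higher (9.53 to 16.6). Smgc (chromosome 15, 91838265 to 91861438) had 162722 and 19936 UMIs, 3.34-fold lower (3.29 to 3.39), and was lower in immune-like cells too. Agr2 had 93 and 0 UMIs, at least 12.7-fold lower. G0s2 was 8.57-fold lower (5.48 to 14.2; -2.57 log2 in immune-like cells), Oit1 4.67-fold (3.35 to 6.69), and Lrrc26 and Kcnn4, genes of potassium channels, each 3.88-fold (2.92 to 5.25). In immune-like cells Fgg, Bnip3 and Trp53inp1 stood at 1.42, 1.02 and 1.0 log2 and Lrrc26 at -2.36, none past the rule. Lcn2 was higher past the rule in those cells too, at 4.12 log2.

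Secretory products of acinar cells had a median of -0.84 at the 0 percentile, with Smgc and Dcpp1 lower past the rule (Dcpp1 stood at 0.13 log2, against -1.81, without the cells with the highest doublet scores), Pip at 0.98 and Car6 at -0.28 log2. Cell cycle inhibitors stood at 0.93 (99.9), with Cdkn1c, Cdkn1a and Gadd45b past the rule at 2.72, 1.85 and 1.22, against -0.15, 1.63 and 1.08 in immune-like cells, where Cdkn1a passed it too. The class held different cell groups in each library: 183 of the wild-type cells lay in a cluster with 5 KO cells and 154 in a cluster with 29, while 137 KO cells lay in another with 1 wild-type cell. Of 3324 genes, 370 were higher and 32 lower past the size rule, with a median over all genes of 0.44 log2; with TMM scaling, which moved that median to -0.09, the split was 112 and 153. For all 21 named genes tried, TMM scaling left the outcome of the size rule unchanged. Most of them were picked for the largest ratios past the rule, so this says little about other genes. In the pair of Smgc-rich acinar-like clusters (186 and 153 cells), Slpi and Lcn2 were again higher and Agr2 at least 15.3-fold lower. Smgc, the gene by which this pair was picked, was 5.94-fold lower (5.85 to 6.02). Of 2409 genes, 239 were higher and 52 lower, with a median over all genes of 0.32 log2. In the pair of Mucl2-rich acinar-like clusters (157 and 29 cells; r = 0.89 across genes, which are not replicates), 23 genes were higher and 21 lower of 1465, with a median over all genes of -0.07 log2. There Mup5 was 6.37-fold higher (6.12 to 6.62), and Smgc 4.73-fold (4.23 to 5.29) and G0s2 10.5-fold lower (5.64 to 22.1). In separate clustering, these Mucl2-rich clusters held 2000819 of 2712918 wild-type and 591468 of 1165454 KO UMIs of acinar-like cells. The cell groups thus weighed differently in the class sums of each library. Whether this set the class median and the split of higher and lower genes was not tested.

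Granular convoluted tubule-like cells (164 wild-type and 566 KO) had lower levels of part of their secretory products in the KO library. Of 19 such genes, 10 were lower past the size rule and 9 did not pass, with a list median of -1.09 at the 0 percentile. Klk1b22, a kallikrein, was 6.41-fold lower (5.97 to 6.89; -1.75 log2 and past the rule in immune-like cells), and Egf, epidermal growth factor, had a log2 ratio of -1.52. Klk1, the most abundant of them with 64222 and 134410 UMIs, stood at -0.61 and Crisp3 at 0.41, neither past the rule. Lcn2 had 3 and 774 UMIs, a ratio of 80.6 (27.5 to 392), and Pdcd4 was 9.84-fold higher (7.89 to 12.4). Ces1d was 5.08-fold (3.83 to 6.88) and Mt1, a metallothionein, 4.52-fold higher (4.24 to 4.82). In immune-like cells Lcn2, Pdcd4 and Mt1 were also higher, by 4.12, 1.21 and 1.27 log2. Socs3, Pik3ip1 and Sesn1 were 7.81-fold (3.89 to 18.3), 11.6-fold (4.42 to 43.0) and 8.36-fold higher (3.17 to 31.2), and stood at 1.2 and 0.60 log2 in immune-like cells for the latter pair; Socs3 had 116 and 841 UMIs there. Cd74 and H2-Ab1, of the MHC class II pathway, were 23.4-fold (13 to 45.5) and 30.7-fold lower (12.3 to 98.9), and in immune-like cells, where they are abundant, they stood at -1.03 and -1.79 log2. Mucl2, Scgb1b27 and Cryab were 7.80-fold, 6.13-fold and 7.88-fold lower, with -1.28, -1.43 and -3.06 in immune-like cells.

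Unfolded protein response genes stood at -0.46 (0.03) in granular convoluted tubule-like cells, none of 18 past the rule, with Hspa5 at -0.49. Of 3987 genes in this class, 67 were higher and 45 lower past the rule. With a total that left out secretory products the split was 40 and 65, as that total moved the median over all genes from 0.16 to 0.01 log2. Most wild-type cells of the class (110) lay in a joint cluster with 2 KO cells, and 446 KO cells in a cluster with 12 wild-type cells.

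Duct-like cells rich in Wfdc18 were compared as a pair of separate clusters, 200 wild-type and 258 KO cells, chosen after the clusters were seen. Ccnd1 was 10.0-fold lower (7.76 to 13.1; -2.97 log2 in immune-like cells), Nkd2, an inhibitor of Wnt signalling, 5.87-fold (4.32 to 8.11; -1.14), and Cdk6, a partner of cyclin D, 6.64-fold (4.06 to 11.4; -0.13). The acinar product genes Prol1 and Car6 were 5.81-fold (5.42 to 6.24) and 5.38-fold higher (4.63 to 6.28), and stood at -1.05 and -0.84 log2 in immune-like cells. Of 4691 genes, 78 were higher and 109 lower past the rule.

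Cell cycle genes were compared over all kept cells, since the question of the series concerns proliferation. Top2a, a DNA topoisomerase of dividing cells, had 125 UMIs in the wild-type and 2 in the KO library, a ratio of 54.2 (14.7 to 452), and Mki67 had 70 and 19. Of 30 cell cycle genes 13 were lower past the size rule and 17 did not pass it, with a list median of -0.55 (0 percentile). Their UMIs together were 4493 and 2329, 1.67-fold lower per UMI in the KO library (1.59 to 1.76). A separate wild-type cluster of 59 cells, left unnamed, held 1882 of these UMIs; its best match in the KO library was the basal duct-like cluster (r = 0.57 across genes, which are not replicates). Joint clustering named its cluster of 57 cycling wild-type cells basal duct-like, with 7 markers at least 2-fold higher, but the stricter filter left it unnamed, and the basal duct-like comparison above held none of these 57 cells. Mki67 UMIs were found in 47 wild-type and 14 KO cells, of which 3 and 9 were immune-like.

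**Figure D4:**
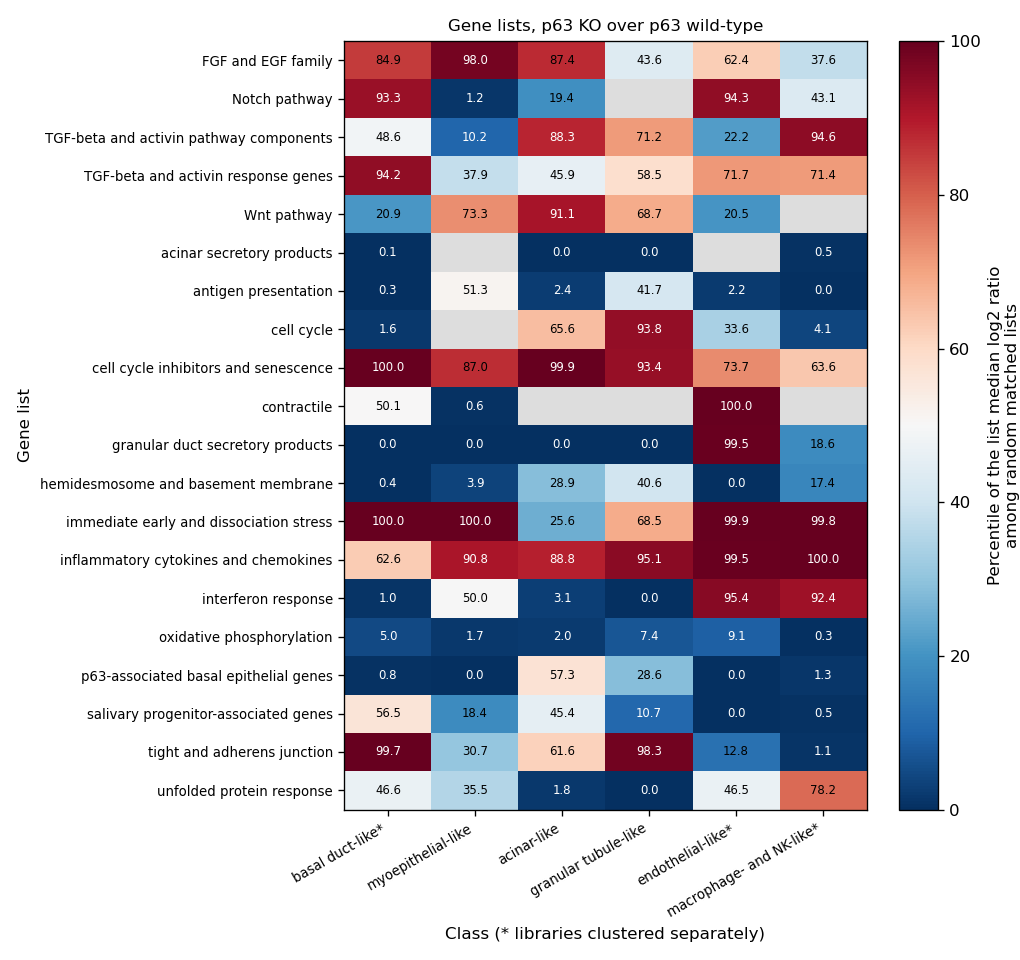
Percentile of each gene list's median log2 ratio (KO over wild-type) among 10000 random matched lists, for 6 cell classes of 1 library per genotype; colours run from 0 (blue) to 100 (red) and grey marks lists with under 5 measured members. Stress genes stand at 99.8 or above in basal duct-like, myoepithelial-like, endothelial-like and immune-like cells, and at 25.6 in acinar-like and 68.5 in granular convoluted tubule-like cells.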

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

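No test was run for the values in this part. They stand here because the barcodes were left out of the class comparisons, except in the alternative with no cell filter. The unnamed cells were left out of the comparisons of joint classes. In the KO library, 40.7% of barcodes (39.3 to 42.1%) had at least 20% mitochondrial UMIs and were removed, against 12.4% in the wild-type library. The 2303 removed KO barcodes held 35.8% mitochondrial UMIs, and Klk1 made up 4.82% and Hbb-bs 11.3% of their other UMIs; the 307 removed wild-type barcodes held 28.6%, 7.65% and 13.1%. Of the kept KO cells, 23.3% lay in joint clusters without a name, against 7.10% of wild-type cells, and 112 of the 117 KO cells named basal duct-like by separate clustering, which the basal duct-like comparison did use, were among them.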

How the results depend on the processing

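Separate clustering without the 4 lists and leaving out the highest doublet scores were chosen after seeing the data. Of 243 alternatives of the leading results, 206 were counted as unchanged, 37 moved and 0 reversed a passed result. The cause was not tested unless given here. Gene list medians gave 106 of these alternatives and 99 of those unchanged. For them, unchanged meant only a percentile on the same side of the limits used above for random lists. The other unchanged alternatives stayed within their interval or within 1.5 times the count. Across the alternatives run, Krt5 stayed 17.0-fold to 21-fold lower in basal duct-like cells and Krt14 2.69-fold to 3.28-fold lower in myoepithelial-like cells. Thinning gave 1.60 for Fst in myoepithelial-like cells (0.549 to 4.50), while with no cell filter it was 3.82 (2.1 to 7.37), an interval beyond 2-fold. Krt14 in basal duct-like cells was 2.07-fold lower after thinning and 2.06-fold at Leiden resolution 2, neither past the rule. The basal duct-like share difference (-27.6 points) was -24.5 with no filter, -22.7 at resolution 2, -17.5 with separate clustering, -20.0 with separate clustering without the lists (joint clustering without them gave -27.8) and -34.7 among epithelial cells. The myoepithelial-like difference (0.919 points) was -0.426, so of the other sign, with no filter, 2.52 with the stricter filter and 3.29 among epithelial cells; the acinar-like one (-13.3) was -20.3 with the stricter filter, where a cluster of 138 KO cells lost its name and 285 and 20 cells were left; the granular convoluted tubule-like one (13.5) was 6.17 with no filter, 6.95 with the stricter filter and 31.7 among epithelial cells. Counts of genes past the size rule in myoepithelial-like (75), acinar-like (402), granular convoluted tubule-like (112) and basal duct-like cells (150) were 25, 131, 62 and 70 with at least 200 UMIs and 172, 890, 282 and 399 at 1.5-fold, both by construction. After thinning they were 17, 114, 48 and 48, with fewer UMIs to count; the acinar-like count was 265 with TMM and 165 with the stricter filter (17 higher and 148 lower, in those fewer cells), which gave 60 in granular convoluted tubule-like cells. With list members of at least 50 UMIs, percentiles were 17.7 for the p63-associated and 3.24 for the contractile list in myoepithelial-like cells, and 4.1 for the p63-associated list in basal duct-like cells. That last list stood at 7.91 at resolution 2 and 2.69 with separate clustering without the lists, and the cell cycle list there at 6.36 with 50 CPM added and 2.95 with TMM. Of the named genes, 1 reversed: Dcpp1 in acinar-like cells stood at 0.13 log2 (-1.81 as reported) without the 5% of cells with the highest doublet scores. After thinning, 14 of 22 named genes in myoepithelial-like and 9 of 22 in basal duct-like cells no longer passed the rule. The other 8 and 13 kept their outcome, whether past the rule or not. In acinar-like cells 10 of 20 and in granular convoluted tubule-like cells 6 of 20 no longer passed it. Leaving out the Scrublet calls removed few cells and says little. Basal duct-like folds were not given for joint clusters, the stricter filter or resolution 0.5, where few KO cells remained. No paired analysis was possible because there was 1 library per genotype.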

Other observations

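Values of other cells come first. Macrophage-like cells of the separate clusters (86 wild-type and 263 KO) held neutrophil genes in the KO library alone: S100a8 had 0 and 1256 UMIs, at least 238-fold higher, S100a9 0 and 857, at least 162-fold, and Ngp and Camp 0 against 171 and 123. Their inflammatory list had a median of 1.08 (100 percentile), with Cxcl2 at 2.23, Ccl3 at 2.13 and Tnf at 1.97 log2, and their antigen presentation list -1.51 (0), with H2-Ab1 at -1.93 and Cd74 at -1.18. These values compare different mixes of cells: in the joint clusters 72 wild-type and 1 KO cells lay in a cluster with 3 dendritic cell genes among its top 10, and 13 and 266 in one with neutrophil genes there. In endothelial-like cells Cyp26b1, a retinoic acid hydroxylase, had 2 and 406 UMIs, a ratio of 81.1 (22.3 to 672), and Foxf1 1 and 62. Here too the cells lay apart: at Leiden resolution 2, 35 wild-type endothelial-like cells lay in a cluster with 0 KO cells, and 261 KO cells in one with 9 wild-type cells and Cyp26b1 among its top 10 genes. Cfd, an adipocyte gene, had 0 and 5772 UMIs over all kept cells, at least 2221-fold higher; adipocyte-like cells numbered 0 and 19.

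All tests in the paragraphs below were chosen only after the results were seen. Krt5 was lower in KO basal duct-like cells. The fold was 17.0 (4.59 to 142) after thinning, which cannot decide on depth, since levels were already per UMI and thinning keeps their expected ratio. Once thinned, 25.3% of wild-type and 1.71% of KO basal duct-like cells held a Krt5 UMI. This argues against depth per cell for the share of cells with Krt5. The Krt5 level in wild-type immune-like cells was 1.67% (up to 6.05%) of that in basal duct-like cells. This argues against free RNA only as gauged in immune-like cells. They had replaced endothelial-like cells, the planned gauge, after wild-type cells of that class were seen to hold Krt14 UMIs. Krt5 in endothelial-like cells is not given here, so free RNA is not settled by this value. In the cells grouped without the listed genes (410 and 112), 72 unlisted genes were at least 4-fold higher in wild-type basal duct-like than other cells. Of these, 83.3% (72.7 to 91.1%) were at least 2-fold higher in the KO class, against 9.10% of other unlisted genes with enough UMIs. This argues against a class wholly of another cell type. Basal markers had named that class, so part of the overlap was given, and some cells of another type stay possible. The separate wild-type basal clusters stood at 301 and 327 Krt5 CPM, and the one with less was still 19.5-fold above the KO class. Krt5 was among the markers that named both, so a wild-type cluster low in Krt5 was less likely to be included. Loss of such a cluster, or of a finer subset, stays open. A hypothesis is that p63 genotype may lower Krt5, as its ratio was 64.9 (11.1 to 2612) in myoepithelial-like cells too, but the Trp63 interval there included 1 (0.978 to 4.22), further KO libraries would be needed to test it, as 1 per genotype cannot separate genotype from other differences.

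Stress genes were higher in KO cells of several classes. The list stood at the 99.9 percentile in endothelial-like cells. Their cell mix differed between the libraries, and those of the wild-type library held Krt14 UMIs, as given above. The value therefore cannot decide whether genotype acted only inside cells with Trp63. In this class the list stayed at 99.9 after thinning (99.94), which cannot decide on depth because the ratios were already per UMI. It stood at 99.8 in endothelial-like cells with under 10% mitochondrial UMIs, which argues against high mitochondrial shares for this class alone. Its main KO cluster had a median share of only 4.22%, and classes with higher shares were not tested. A difference in handling may explain the pattern, since immune-like cells, whose cell mix differed, stood at 99.8 (99.77). If handling shifted every class alike, acinar-like and granular convoluted tubule-like cells would be shifted too, but they stood at 25.6 and 68.5. Whether handling acts alike in each class was not tested, and the acinar-like class held different cell groups in each library. Ionocyte-like cells, whose clusters did not pair, stood at 0. The part of handling stays open with 1 library per genotype.

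Cell cycle UMIs were fewer in the KO library among the 1428 and 1582 cells outside the non-epithelial classes, unnamed cells included. The fold was 1.73 (1.55 to 1.93) after thinning, which cannot decide on depth, since the fold is per UMI and thinning keeps its expected value. Whether the filter took cycling cells from the KO library stays open: the removed barcodes gave 1.14 (0.964 to 1.35), and a fold of 1.98 (1.89 to 2.07) over all barcodes, computed after that, rises with their mitochondrial UMIs and decides nothing. The fold rests on a cluster of 59 cycling wild-type cells, unnamed in separate clustering while joint clustering named such a cluster basal duct-like, as without it the fold was 0.993 (0.932 to 1.06), a value that is no test because the list itself picks the cluster. A hypothesis is that genotype may lower proliferation. The Top2a ratio of 54.2 (14.7 to 452) is no separate support, because Top2a belongs to the same list. Further KO libraries would be needed to test it, and it stays open with 1 library per genotype.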
